A study of Mus musculus with 12 samples.

How the data were processed

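Cardiomyocyte RNA of male mice was measured in 12 libraries, 3 in each of 4 groups defined by genotype (control or dKO) and surgery (sham or TAC). Per the labels' protocols, mice received 3 daily tamoxifen injections of 30 ug/g at 8 weeks of age, surgery followed at 10 weeks and hearts were isolated 7 days later at 11 weeks. The series' design text gives 8 weeks for the surgery, and which age is right is not given in the sources used here. Cells were released by Langendorff perfusion, cardiomyocytes were separated by sedimentation for 10 min at 37 °C, and libraries were made from 200 ng of RNA with a stranded poly(A) kit and read as single ends of 100 nt, per the labels' protocols. Sedimentation enriches cardiomyocytes and can leave other cells, so lists of their markers were included.

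The deposited table holds raw read counts per gene as whole numbers for 49568 genes, and 21344 genes had no count in any library. Per the submitters' processing notes the tools were Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.0p3 and featureCounts, with genome GRCm38.p5. Their settings, the gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Genes were matched by symbol, or by a unique synonym in the RefSeq gene table, to GENCODE mouse release 21 on GRCm38 for identifiers, coordinates and exon lengths, and 14554 of 14712 tested genes matched.

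The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with TMM normalization and the filterByExpr rule by group, which left 14712 genes. All 12 libraries entered 1 fit with a mean per group and 8 residual degrees of freedom. The comparisons were TAC against sham in control and in dKO, dKO against control after sham and after TAC, and the interaction, coded as the TAC effect in dKO minus that in control. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are log2 values, with an SE taken from the size of the log2 change and its F statistic. An SE of a list median, or of a difference between list medians, is instead taken over the genes of the lists. It leaves out the spread between libraries. Levels are CPM on TMM-scaled library sizes. Totals per library lay between 20082000 and 29675212, so a floor of 3 counts corresponded to 0.0935 to 0.184 CPM, which covers counting error only. No library pair within a group was a duplicate.

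The comparisons, alternatives, the 34 gene lists and the rule for naming genes were fixed before the data were examined. In each comparison the rule names Mkl1, Mkl2, Myocd, Srf, Nppa, Nppb, Myh7, Myh6 and Acta1. It adds up to 5 called genes with the highest and 5 with the lowest log2 change, at a mean of at least 5 CPM and with no overlap between groups, leaving out predicted genes and pseudogenes, and the 3 called members with the smallest p of each of the 8 lists with the smallest p. Other genes named were chosen after their values were seen.

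Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset to 0.01, with Benjamini-Hochberg adjustment over 170 list tests. Of these, 68 were called, 2 of them with an estimated correlation, and fry called 2. Both were the fetal and hypertrophic program after TAC, in control and in dKO. Fry tests whether the genes of a list move one way on balance and compares them with no other genes. Beside each list stands its number of genes past the threshold over all genes and adjusted over the list alone. Listed genes that were too low to be tested numbered 9 of the blood list, 4 of the mitochondrially encoded list, 2 of the atrial list and 1 each of the glycolysis, nerve and epicardial, oxidative stress and cytokine lists. Of MRTF-SRF targets 15 genes, of the fetal program 10, of atrial markers 3 and of YAP-TEAD targets 4 are also in another list, and no gene of the matrix, fibroblast, endothelial or macrophage lists is.

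Transcript length was examined in nuclear protein-coding genes with a mean of at least 5 CPM by correlating exon length with each library's deviation from the other replicates of its group. Near-identical copies were searched with blastn 2.17.0 among annotated transcripts for the genes called in the same direction in dKO after sham and after TAC. Nppb, called after sham only, was not searched. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

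The steps were tested on simulated counts with 200 genes changed, 100 of them 2-fold and 100 of them 4-fold. Of 2-fold changes 27% were recovered for TAC in control (14556 genes), 20% for TAC in dKO (14551), 25% for dKO after sham (14527) and 26% for dKO after TAC (14551), and of 4-fold changes 88%, 89%, 86% and 86%. The interaction recovered 2% and 50% (14551 genes). False calls numbered 4, 9, 4, 11 and 1. Camera called 3 of 3 changed lists and 0 of 167 unchanged ones. The simulated genes were drawn independently, so these values cannot show how often camera calls unchanged lists whose genes move together.

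Alternatives were other normalizations, DESeq2 1.42.0, limma-voom with and without sample quality weights, other expression filters, counts without mitochondrially encoded genes, fits of only the groups compared, the replicate number as a block and leaving out each library in turn. Leaving out the 2 libraries with the strongest transcript-length trend, dKO sham replicate 1 and dKO TAC replicate 2, and removing each library's trend with length were added after seeing the data.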

Results

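RNA from cardiomyocytes of male mouse hearts was sequenced in 4 groups of 3 libraries: control sham, control TAC, dKO sham and dKO TAC. TAC is a surgical narrowing of the aorta that loads the left ventricle with pressure, and sham is the same surgery without the narrowing. The dKO mice lacked myocardin-related transcription factor A in all cells and lost factor B, encoded by floxed Mkl2, from cardiomyocytes after tamoxifen. Control mice carried the same tamoxifen-inducible Cre transgene with intact factors, whose genes are named Mkl1 and Mkl2 in the table. Hearts were taken 7 days after surgery. Total counts per library lay between 20082000 and 29675212. The total was 23630354 to 29675212 in control sham, 25633373 to 28007352 in control TAC, 20082000 to 28600089 in dKO sham and 23784132 to 27635230 in dKO TAC. Mitochondrially encoded genes took 31.01% ± 1.57 (SD, n = 3) of counts in control sham, 25.36% ± 2.1 in control TAC, 24.77% ± 7.16 in dKO sham and 21.49% ± 5.37 in dKO TAC. The wide spread in the dKO groups came from dKO sham replicate 1, at 16.51%, and dKO TAC replicate 2, at 15.32%. The same libraries stood apart from their group in how counts changed with transcript length. In the 9748 genes examined, the deviation from the other replicates fell with length in dKO sham replicate 1 (Spearman rho across genes -0.62) and in dKO TAC replicate 2 (-0.595), against -0.103 to 0.114 in the control libraries. Genes with transcripts of at most 1963 nt were higher in dKO sham replicate 1 by a median log2 of 1.11, and those of at least 10502.6 nt were lower, at -0.88. The other dKO libraries trended the opposite way, from 0.455 to 0.646, since each was compared with a group holding the odd library.

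**Figure D1:**
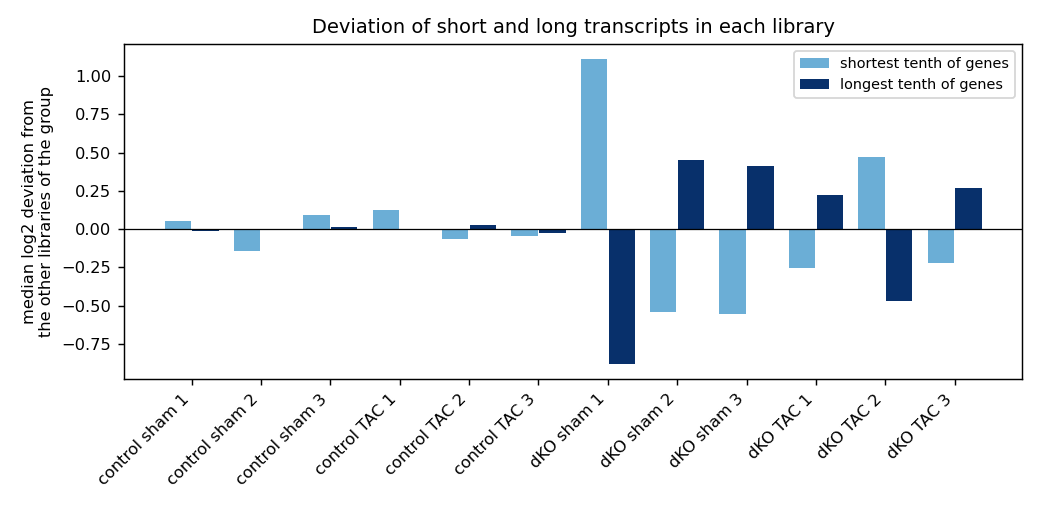
Median log2 deviation of each library from the other replicates of its group, for transcripts of at most 1963 nt and of at least 10502.6 nt. In dKO sham replicate 1 the shortest lie at 1.11 and the longest at -0.88, while control libraries stay near 0.

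The targeted genes were examined first, in every library. Mkl1, on chromosome 15 from 81012281 to 81190757 (GRCm38, protein coding), had 7.59, 11.4 and 8.89 normalised read counts (CPM, counts scaled to a common library size) in control sham and 9.32, 16 and 15.6 in control TAC. It had 2.15, 2.88 and 3.2 in dKO sham and 2.5, 2.93 and 2.22 in dKO TAC. All 6 dKO libraries thus lay below all 6 control libraries. Mkl1 was lower in dKO after sham (log2 -1.75 ± 0.27, SE) and after TAC (-2.42 ± 0.27). The adjusted p-values (edgeR quasi-likelihood test, Benjamini-Hochberg) were 0.0409 and 0.00182. Mkl2, on chromosome 16 from 13256481 to 13417529, had 44.1, 32.6 and 44.1 CPM in control sham, 36, 30.1 and 37 in control TAC, 15.2, 26.5 and 23.9 in dKO sham, and 28.1, 18.1 and 24.5 in dKO TAC. Its estimates were -0.88 ± 0.23 after sham and -0.54 ± 0.23 after TAC, with edgeR Benjamini-Hochberg adjusted p of 0.507 and 0.518. Counts over the whole gene also include exons outside the floxed part and reads from other cells, so the Mkl2 level is a weak check of the deletion. The Mkl1 call after sham was lost without any 1 library except control TAC replicate 1, with an edgeR Benjamini-Hochberg adjusted p for Mkl1 of 0.151 without control sham replicate 2, 0.16 without dKO sham replicate 2 and 0.135 without control sham replicate 3, and between 0.0531 and 0.0864 without any of the others. Its call after TAC held without each library. Myocd, the related cardiac cofactor of serum response factor, did not pass in any comparison.

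**Figure D2:**
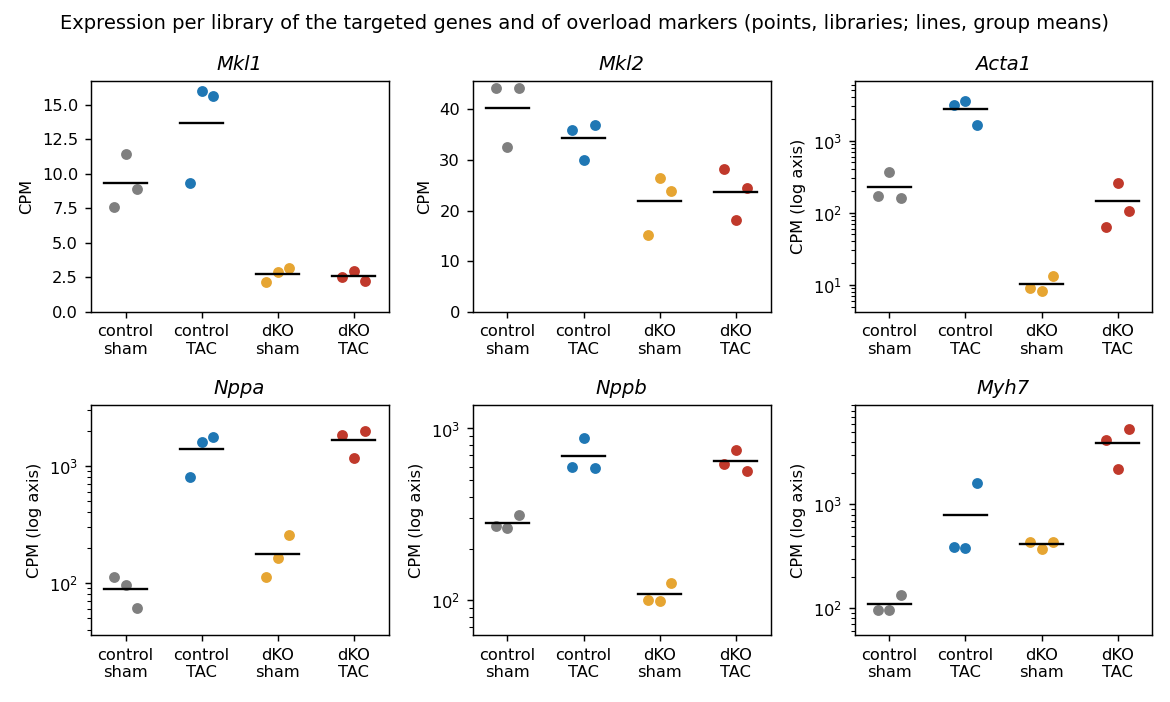
CPM of targeted and cardiac stress genes in each of the 12 libraries (points), with group means (lines), on linear axes from 0 for Mkl1 and Mkl2 and log axes for the others. Mkl1 lies between 2.15 and 3.2 in the 6 dKO libraries and at or above 7.59 in the 6 control libraries.

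The first comparison asked how control cardiomyocytes responded to pressure overload. Of 34 extracellular matrix genes 23 rose after TAC, of 22 cell cycle genes 14 and of 18 genes of the fetal and hypertrophic program 9, at an adjusted p = 0.728, 0.728 and 0.0459 with an estimated correlation (camera, Benjamini-Hochberg). Nppa, which encodes atrial natriuretic peptide, rose from 89.8 to 1391 CPM, 15.5-fold. Myh7, the slow myosin heavy chain, rose from 109 to 790 CPM, and skeletal actin Acta1 rose from 230 to 2784 CPM. Periostin (Postn), a matrix protein of activated fibroblasts, rose from 33.8 to 1088 CPM, and the proliferation marker Mki67 rose by a log2 of 3.57. In all, 280 genes were higher and 51 lower among 14712 tested (adjusted p under 0.05, edgeR quasi-likelihood test with Benjamini-Hochberg), of which 273 and 41 changed at least 2-fold.

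Among genes fixed for every comparison, log2 changes in control after TAC were 3.95 ± 0.42 (SE) for Nppa, 1.28 ± 0.22 for Nppb, 2.86 ± 0.53 for Myh7 and 3.60 ± 0.55 for Acta1. Their edgeR Benjamini-Hochberg adjusted p-values were 0.00452, 0.0157, 0.0204 and 0.0125. Myh6, the fast adult myosin heavy chain, had 25470 CPM after sham and 19890 after TAC, a log2 estimate of -0.36 that did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.652). Srf stayed at 96.9 and 94.7 CPM and did not pass. The highest ranked genes with no overlap between groups were Sprr1a (0.131 to 31.5 CPM), the matrix genes Cthrc1 (0.172 to 26.3 CPM) and Col8a2 (0.165 to 16 CPM), all near 3 counts per library after sham, so that no fold is given, Ltbp2 (log2 5.89 ± 1.03) and Cilp (5.43 ± 0.97). Among the lowest were the potassium channel subunit Kcnv2 (-2.27 ± 0.51), Klhl38 (-1.86 ± 0.38), the glycolytic regulator Pfkfb1 (-1.81 ± 0.29) and the mitochondrial transfer RNA gene mt-Ti (-1.78 ± 0.33). The edgeR Benjamini-Hochberg adjusted p-values of these 9 genes lay between 0.0146 for Pfkfb1 and 0.0407 for Kcnv2.

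Of the 34 extracellular matrix genes, 23 rose, 0 fell and 11 did not pass, and 33 rose when adjusted over the list alone. Thbs4 rose by 4.88, Postn by 5.01, and Spp1 from 0.0857 CPM, under 3 counts per library on average, to 6.78. The list median was 2.92, with a camera Benjamini-Hochberg adjusted p of 4.5e-26, or adjusted p = 0.728 with an estimated correlation. Of 22 cell cycle genes, 14 rose and 8 did not pass (19 adjusted over the list alone), including Mki67, Cdca8 (3.39) and Cenpe (2.98), with a list median of 2.51 and an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). Of 18 genes of the fetal and hypertrophic program, 9 rose and 9 did not pass (16 adjusted over the list alone), with a median of 1.57. Mybpc2, a skeletal muscle myosin-binding protein, rose by 2.02 ± 0.18, Ankrd1 by 1.75 ± 0.30 and Fhl1 by 1.5 ± 0.30. This list kept its call with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.0459). Of 35 MRTF-SRF cytoskeletal targets, 5 rose (13 adjusted over the list alone): Acta1, Ankrd1, Fhl1, Cnn1 and Zyx. Their median was 0.81, and the adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg).

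Markers of some other cells had higher estimates in the same libraries. Of 16 fibroblast markers 4 rose (9 adjusted over the list alone), among them Cilp and Mfap5 (2.89), with a median of 1.15 and a median level of 13.3 CPM after sham and 42.7 after TAC. Of 21 macrophage markers 0 passed over all genes by edgeR and 18 were higher adjusted over the list alone, with a median of 1.3. All 21 had positive estimates. Atrial markers had a median of 2.27, with Nppa and Dkk3 past the test of 8 measured (3 adjusted over the list alone). These 3 lists had an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). Endothelial markers (median 0.05), pericyte and smooth muscle markers (0.06), nerve and epicardial markers (0.29) and blood and lymphocyte markers (-0.71, with 2 of 7 positive) were not called by camera, and of these only Cnn1 rose. Control TAC replicate 1 held less matrix RNA than the other replicates, at 136 CPM of Postn against 763 and 2364. Cytokine genes had a median of 0.92, with Serpina3n (2.69) and Lcn2 (1.43) past the test of 21 (4 adjusted over the list alone). Interferon response genes had a median of 0.66, with 2 of 19 past the test, Cxcl10 (2.99) and Oasl2 (1.13), and 3 adjusted over the list alone. The cytokine and interferon lists had an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). Without control TAC replicate 3 the fibroblast, macrophage and cytokine medians were 0.62, 0.77 and 0.29, and the atrial median was 1.45 without control TAC replicate 1, all still called by camera.

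Genes of mitochondrial fuel use had lower estimates, with none of them past the test over all genes by edgeR. Of 30 fatty acid oxidation genes 29 had negative estimates, with a median of -0.62 and 0 called when adjusted over the list alone. The tricarboxylic acid cycle and branched-chain amino acid list had a median of -0.39 (2 of 22 lower adjusted over the list alone), and all 45 nuclear oxidative phosphorylation genes had negative estimates, with a median of -0.28 and 0 called when adjusted over the list alone. The 9 mitochondrially encoded genes measured had a median of -0.45 (1 lower adjusted over the list alone), and their share of all counts was 25.36% against 31.01% after sham. Of 20 potassium and pacemaker channel genes Kcnv2 fell and 7 were lower adjusted over the list alone, with a median of -0.55. Actin dynamics genes had a median of 0.45 (2 of 30 higher adjusted over the list alone), microtubule genes 0.59 (0 of 18), costamere genes 0.28 (3 of 31 rose, and 3 higher and 1 lower adjusted over the list alone) and atrophy and autophagy genes -0.19 (0 of 21). All the lists of this paragraph were called by camera, and none with an estimated correlation, at Benjamini-Hochberg adjusted p-values of 0.728, 0.831 for atrophy and 0.938 for oxidative phosphorylation. The costamere call was lost without control sham replicate 2, control TAC replicate 1 or control TAC replicate 2 (camera, Benjamini-Hochberg adjusted p of 0.088, 0.0857 and 0.101), and the atrophy call without control sham replicate 1, control TAC replicate 2 or control TAC replicate 3 (0.125, 0.0522 and 0.0778). Other medians moved while their lists stayed called: those of oxidative phosphorylation, mitochondrially encoded and tricarboxylic acid cycle genes to -0.45, -0.71 and -0.58 without control TAC replicate 1, the last to -0.25 without control TAC replicate 3, that of microtubule genes to 0.39 without control sham replicate 1 and 0.31 without control TAC replicate 2, and that of actin dynamics genes to 0.68 without control sham replicate 2. With the transcript-length trend removed the mitochondrially encoded list was not called (camera, Benjamini-Hochberg adjusted p = 0.0551).

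**Figure D3:**
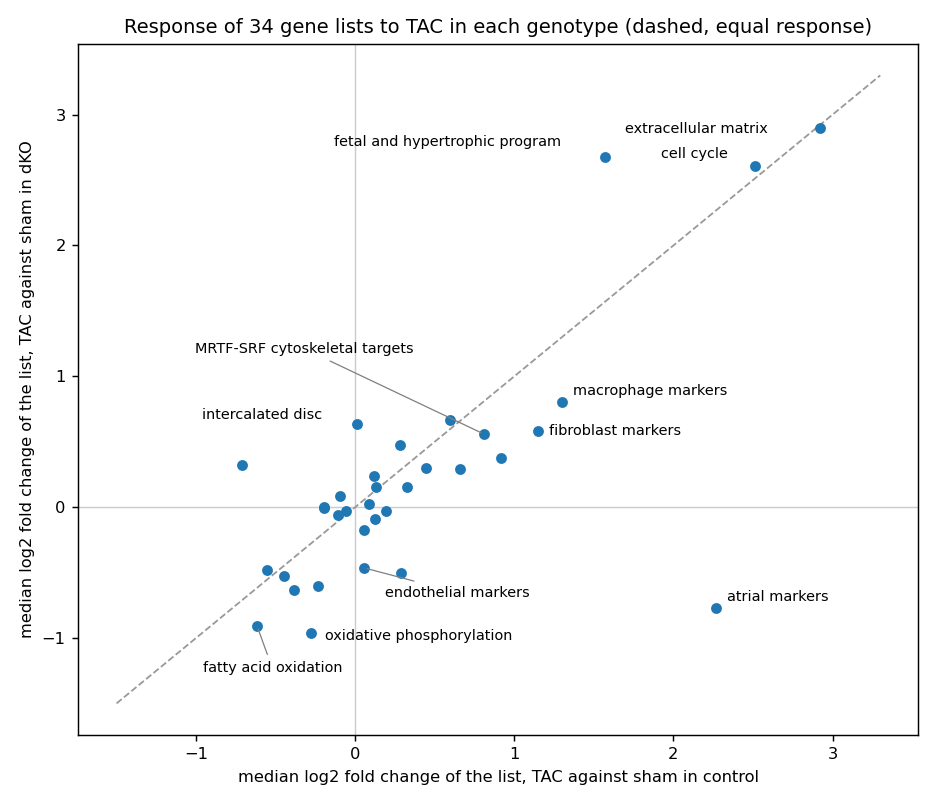
Median log2 change after TAC of each gene list in control (x axis) and in dKO (y axis), with a line where both would be equal. The extracellular matrix list lies at 2.92 in control and 2.90 in dKO.

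The number of genes called after TAC in control depended on single libraries. The total, 331 with all libraries, was 2 without control sham replicate 1, 3 without control sham replicate 3, 14 without control TAC replicate 2, 109 without control TAC replicate 3 (95 of them among the 331) and 1130 without control TAC replicate 1 (327 among the 331). It was 723 without dKO sham replicate 1, 208 without dKO sham replicate 2, 176 without dKO TAC replicate 1 and 201 without dKO TAC replicate 3, and genes lower numbered 83 without control sham replicate 2, 31 without dKO TAC replicate 2 and 28 without dKO sham replicate 2. The calls of Nppb, Myh7 and Acta1 were lost without control sham replicate 1 (edgeR, Benjamini-Hochberg adjusted p of 0.108, 0.124 and 0.088), control sham replicate 3 (0.0989, 0.114 and 0.0989) or control TAC replicate 2 (0.0655, 0.0524 and 0.0563), and that of Nppa held without each library. Without dKO sham replicate 1 and dKO TAC replicate 2 together, 501 genes were higher and 270 lower, and 322 of the 331 remained. With only the 2 groups compared in the fit, 2 genes were higher and 0 lower (edgeR), against 699 and 239 with DESeq2 on all libraries, 2480 genes at an unadjusted p under 0.05 in the fit of all libraries, and 141 higher with limma-voom.

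The second comparison asked the same of dKO cardiomyocytes. Of 34 matrix genes 23 rose after TAC, of 22 cell cycle genes 16 and of 18 fetal and hypertrophic genes 15, at an adjusted p = 0.728, 0.728 and 0.0459 with an estimated correlation (camera, Benjamini-Hochberg). Nppa rose from 178 to 1664 CPM, 9.35-fold, Nppb from 109 to 647, Myh7 from 413 to 3921 and Ankrd1 by a log2 of 3.40. Acta1 rose from 10.2 to 144 CPM, which left it below the 230 CPM of control sham. Of 30 fatty acid oxidation genes 10 fell, Ech1 and Acaa2 among them, with an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). In all, 618 genes were higher and 469 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 493 and 357 changed at least 2-fold.

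In dKO after TAC the log2 changes were 3.23 ± 0.41 (SE) for Nppa, 2.57 ± 0.22 for Nppb, 3.25 ± 0.54 for Myh7 and 3.82 ± 0.56 for Acta1. Their edgeR Benjamini-Hochberg adjusted p-values were 0.00217, 0.000342, 0.00683 and 0.0041. Myh6 had 23130 CPM after sham and 12270 after TAC, an estimate of -0.91 (edgeR, Benjamini-Hochberg adjusted p = 0.092). The highest ranked genes were Sprr1a (8.27 ± 1.29), Cthrc1 (0.181 to 14.2 CPM, near 3 counts per library after sham), Col12a1 (5.26), Star, which moves cholesterol into mitochondria for steroid synthesis (5.26 ± 0.52), and Ltbp2 (5.17). Sprr1a had 0.18 to 0.828 CPM in dKO sham, so the size of its fold is uncertain. The lowest were Cyp26b1, which degrades retinoic acid (-4.73 ± 1.08), Ces1d (-3.35), mt-Ti (-3.06), the kinase gene Mylk4 (-2.65 ± 0.33) and Phkg1 (-2.48). Their edgeR Benjamini-Hochberg adjusted p-values included 0.000602 for Star and 0.0242 for Cyp26b1.

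Of 34 matrix genes 23 rose and 11 did not pass (33 adjusted over the list alone), with a median of 2.90, and Thbs4 at 5.03, Col8a1 at 3.89 and Postn at 4.91. Of 22 cell cycle genes 16 rose (21 adjusted over the list alone), with Mki67 at 2.85, Nusap1 at 3.13 and a median of 2.61. Both calls were lost, with an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). Of 18 fetal and hypertrophic genes 15 rose (15 higher and 1 lower adjusted over the list alone), with a median of 2.68. Mybpc2 rose by 2.06, and the intercalated disc gene Xirp2 by 3.01 ± 0.34. The list kept its call, at an adjusted p = 0.0459 with an estimated correlation (camera, Benjamini-Hochberg). Without dKO sham replicate 1 and dKO TAC replicate 2, matrix, cell cycle and fetal genes higher numbered 13, 11 and 14.

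Of 30 fatty acid oxidation genes 10 fell (22 adjusted over the list alone), among them Ech1 (-1.94 ± 0.40), Eci1 (-1.66) and Acaa2 (-1.67), with a median of -0.91. Of 22 genes of the tricarboxylic acid cycle and branched-chain amino acid list 3 fell, Bckdha (-1.47), Bckdhb (-1.09) and Idh2 (-1.07), and 10 were lower adjusted over the list alone, with a median of -0.63. Of 45 oxidative phosphorylation genes only Cox7a1 (-1.89 ± 0.49) fell over all genes by edgeR and 38 were lower adjusted over the list alone, with a median of -0.96. These short transcripts were high in dKO sham replicate 1, where Cox7a1 had 2361 CPM against 614 and 570. Genes of the other lists were high there too: Ech1 had 3273 CPM against 1413 and 1265, Bckdha 661 against 280.4 and 242.5, and Idh2 3418 against 2021 and 1882. Without that library and dKO TAC replicate 2 the oxidative phosphorylation median was -0.47 with 7 genes lower, and 7 fatty acid oxidation genes were lower. Of the tricarboxylic acid cycle and branched-chain amino acid list 1 gene was then lower. The 9 mitochondrially encoded genes had a median of -0.53, with 0 called when adjusted over the list alone, and lost their camera call without dKO TAC replicate 2 (-0.43, Benjamini-Hochberg adjusted p = 0.267), without dKO sham replicate 2 (-0.45, 0.117) or dKO sham replicate 3 (-0.50, 0.0758), and with the transcript-length trend removed (-0.18, 0.64). Their median was -0.82 without dKO TAC replicate 1. Those of the oxidative phosphorylation and tricarboxylic acid cycle lists were -0.35 and -0.39 without dKO sham replicate 1, both still called. All 4 lists had an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg).

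Of 20 intercalated disc genes 4 rose (8 adjusted over the list alone), with a median of 0.63, among them Pkp2 (0.78) and Cxadr (0.90). Of 31 costamere genes 4 rose and 1 fell (10 higher and 2 lower adjusted over the list alone), with a median of 0.48, including Itga5 (1.19), Flnc (1.3) and Lims2 (-0.83). Of 35 MRTF-SRF targets 6 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.56, and Pdlim5 (1.17) and Smtn (-0.88) among them. Of 30 actin dynamics genes 5 rose (7 adjusted over the list alone), with a median of 0.30, and of 18 microtubule genes 4 rose (6 adjusted over the list alone), with a median of 0.67. Of 20 potassium and pacemaker channel genes 5 fell (7 adjusted over the list alone), with a median of -0.48. These lists had an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). YAP-TEAD targets had a median of 0.24, with 4 of 20 higher (5 adjusted over the list alone) and an adjusted p = 0.736 with an estimated correlation (camera, Benjamini-Hochberg). Of the markers of other cells, fibroblast markers had a median of 0.58 (4 of 16 rose, Scara5 fell, and 5 rose and 1 fell adjusted over the list alone), macrophage markers 0.80 and endothelial markers -0.46, the last 2 with 0 genes called by edgeR, adjusted over the list alone as well. Cytokine genes had a median of 0.38 (2 of 21 rose, and 3 adjusted over the list alone). These 4 lists had an adjusted p = 0.866 with an estimated correlation (camera, Benjamini-Hochberg). Leaving out dKO TAC replicate 2 ended the calls of MRTF-SRF targets (median 0.40), microtubule genes (0.33), potassium and pacemaker channel genes (-0.32), fibroblast markers (0.49), macrophage markers (0.58) and cytokine genes (0.16), at camera Benjamini-Hochberg adjusted p-values of 0.0624, 0.177, 0.112, 0.0585, 0.082 and 0.263. Leaving out dKO sham replicate 1 ended those of YAP-TEAD targets (0.06), fibroblast markers (0.51) and cytokine genes (0.26), at 0.376, 0.111 and 0.143. The endothelial call was lost without dKO sham replicate 3 (0.224) or dKO TAC replicate 3 (0.171). With both odd libraries left out the medians of MRTF-SRF targets (0.177), microtubule genes (0.398) and endothelial markers (-0.795, with 6 genes lower) were still called by camera. Those of macrophage markers (0.39), fibroblast markers (0.468), potassium and pacemaker channel genes (-0.40), YAP-TEAD targets (0.16) and cytokine genes (-0.128) were not, at Benjamini-Hochberg adjusted p-values of 0.173, 0.262, 0.139, 0.343 and 0.537. Microtubule genes also lost their call without dKO sham replicate 2 (0.1) or dKO sham replicate 3 (0.0758), and potassium and pacemaker channel genes without dKO sham replicate 2 (0.0605). Medians that moved up while called were those of YAP-TEAD targets (0.36 and 0.37 without dKO sham replicates 2 and 3), cytokine genes (0.62 without dKO sham replicate 3) and actin dynamics genes (0.45 without dKO TAC replicate 3).

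The total of genes called after TAC in dKO, 1087 with all libraries, was 210 without dKO TAC replicate 1, 306 without dKO TAC replicate 3 (304 of them among the 1087) and 661 without dKO sham replicate 2 (603 among the 1087). Genes lower numbered 732 without dKO sham replicate 3. With dKO sham replicate 1 and dKO TAC replicate 2 left out, 885 were higher and 695 lower, and 766 of the 1087 remained.

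The 2 responses were then set side by side. Across the 14712 genes, which are not independent replicates, the fitted changes correlated with Pearson's r of 0.705 and Spearman's rho of 0.606, with a slope of dKO on control of 0.794, and 10370 genes had the same sign. The 2 responses share no library. Of the 280 genes higher in control, 279 had the same sign in dKO, with medians of 2.54 in control and 2.26 in dKO. All 51 genes lower in control had negative estimates in dKO, with medians of -1.49 and -1.37. Of the 618 genes higher in dKO, 597 had the same sign in control, with medians of 1.18 in control and 1.75 in dKO. Of the 469 genes lower in dKO, 451 did, with medians of -0.639 and -1.34. Each set had the larger median in the genotype that chose it, so these medians do not show which response was stronger. In both genotypes 209 genes were higher, against 11.8 for independent lists, and 30 were lower, against 1.63.

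The difference between the responses was tested as the interaction of genotype and TAC. No gene passed: edgeR called 0 higher and 0 lower, with a smallest Benjamini-Hochberg adjusted p of 0.515 and 697 genes at an unadjusted p under 0.05. DESeq2 called 8 and 3, limma-voom none, and limma-voom with sample quality weights 1157 and 1342. The natriuretic peptide gene Nppb had an estimate of 1.29 ± 0.30 (SE), Nppa -0.73, Myh7 0.39 and Acta1 0.22 ± 0.70. Their edgeR Benjamini-Hochberg adjusted p was 0.841 for Nppb and Nppa, 0.906 for Myh7 and 0.948 for Acta1. Of the gene lists, intercalated disc genes had the smallest p: 19 of 20 had positive estimates, with a median of 0.51, among them Cdh2 (1.13), Pkp2 (0.77) and Xirp2 (1.43), and 0 passed by edgeR, also adjusted over the list alone. Its camera Benjamini-Hochberg adjusted p was 9.5e-07, and the adjusted p = 0.728 with an estimated correlation. In simulated data the interaction test recovered 2% of 2-fold and 50% of 4-fold differences. Without dKO sham replicate 1 and dKO TAC replicate 2 it called 2 genes higher, Prkab2 (2.73) and Dync1li1 (1.23), which were named after their values were seen, and without dKO TAC replicate 2 alone it called 1 gene higher.

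The third comparison asked what loss of the factors changed without overload. In dKO sham, Acta1 had 10.2 CPM against 230 in control sham, and Nppb 109 against 283. Ndufs5, which encodes a subunit of respiratory complex I, had 1.66 against 41.9. Together with Mkl1 these were the 4 genes lower, and 6 genes were higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 1361 at an unadjusted p under 0.05. The log2 differences were -4.50 ± 0.58 (SE) for Acta1, -1.38 ± 0.22 for Nppb and -4.73 ± 0.41 for Ndufs5, with edgeR Benjamini-Hochberg adjusted p-values of 0.0102, 0.0458 and 0.000459. Myh7 had 413 CPM in dKO sham and 109 in control sham, an estimate of 1.92 ± 0.51 that did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.507).

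The 6 genes higher in dKO sham were BC002163, Eif3j2, Gm14085, Gm16399, Gm20305 and Rpl3-ps1. Each is a near-identical copy of another tested gene, so each is uncertain. BC002163, a processed pseudogene on chromosome 16 from 42955631 to 42955949, matched Ndufs5 (chromosome 4 from 123712710 to 123718202) at 99.4% over 319 nt, and had 1 CPM in control sham and 130 in dKO sham while Ndufs5 had 41.9 and 1.66. Eif3j2 matched Eif3j1 at 99.4%, with 0.341 and 8.08 CPM for Eif3j2 and 26.2 and 12 for Eif3j1. Rpl3-ps1 matched Rpl3 at 99.8%, Gm20305 matched Polr2k at 99.4%, Gm14085 matched Slc28a2 at 95.9% and Gm16399 matched Cox6c at 95.3%. The low Ndufs5 count is uncertain for the same reason.

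Of 35 MRTF-SRF targets only Acta1 fell in dKO sham (1 adjusted over the list alone), and 27 had negative estimates, with a median of -0.28. The camera Benjamini-Hochberg adjusted p was 0.00137, and the adjusted p = 0.728 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.62 with 43 of 45 positive, 0 past the test by edgeR and 0 adjusted over the list alone, and an adjusted p = 0.866 with an estimated correlation (camera, Benjamini-Hochberg). That median was -0.04 without dKO sham replicate 1, the library rich in short transcripts. Glycolysis genes had a median of 0.41 with 0 of 23 called, and of 0.06 without that library and dKO TAC replicate 2 (camera, Benjamini-Hochberg adjusted p = 0.0521). Of 7 blood and lymphocyte markers 5 were lower adjusted over the list alone and 0 over all genes by edgeR, with a median of -2.40 and 33.8 CPM of the globin gene Hbb-bs in control against 4.88 in dKO. Both lists had an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). Small negative medians were called by camera for mitochondrially encoded genes (-0.45), YAP-TEAD targets (-0.34), potassium channel genes (-0.24), intercalated disc genes (-0.23) and cardiac transcription factors (-0.22, with Mkl1 lower over all genes and 2 genes adjusted over the list alone). In the other 4 of these lists 0 genes passed over all genes by edgeR or adjusted over the list alone. With an estimated correlation their camera Benjamini-Hochberg adjusted p was 0.728, 0.736, 0.728, 0.866 and 0.728. Without dKO sham replicate 1 the intercalated disc median was -0.03 and the YAP-TEAD median -0.135, neither called (camera, Benjamini-Hochberg adjusted p of 0.372 and 0.321). In the absence of control sham replicate 3 the cardiac transcription factors stood at -0.11 and the potassium channel genes at -0.21, neither called (0.18 for both). These 2 calls were also lost without control sham replicate 1 (0.0958 and 0.117), dKO sham replicate 2 (0.0613 and 0.0582) or dKO sham replicate 3 (0.121 and 0.202). The intercalated disc call was lost without control sham replicate 1 (0.0958) or 3 (0.175) too, and the YAP-TEAD call without control sham replicate 3 (0.056). The MRTF-SRF median was -0.42 without control sham replicate 1, the intercalated disc median -0.36 without control sham replicate 2, and the medians of potassium channel genes and cardiac transcription factors -0.14 and -0.09 without dKO sham replicate 1, all called. With the transcript-length trend removed the medians were -0.713 for mitochondrially encoded and 0.201 for oxidative phosphorylation genes, both called, and -0.152, -0.188 and -0.103 for intercalated disc genes, YAP-TEAD targets and cardiac transcription factors, not called. The genes lower numbered 1 without dKO sham replicate 2 and 2 without any 1 of control sham replicates 1, 2 and 3, control TAC replicate 3, dKO sham replicates 1 and 3 and dKO TAC replicates 1 and 2, and 10 genes were higher without dKO sham replicate 3. Nppb lost its call without any 1 library except control TAC replicate 2, at an edgeR Benjamini-Hochberg adjusted p between 0.0508 and 0.257. That of Acta1 was 0.0537 without dKO sham replicate 1 and 0.0888 without dKO sham replicate 2.

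The last comparison asked what loss of the factors changed under overload. Acta1 had 144 CPM in dKO TAC and 2784 in control TAC, and the calponin gene Cnn2 was lower by a log2 of -1.56. Genes higher in dKO TAC included Lcn2, which encodes the secreted iron-carrier-binding protein lipocalin 2, and Gpx3, the plasma glutathione peroxidase, at 1318 CPM against 295. The coxsackievirus and adenovirus receptor gene Cxadr of the intercalated disc was also higher, at 64.3 against 26.2 CPM. In all, 45 genes were higher and 18 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 42 and 17 by at least 2-fold.

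The log2 differences in dKO after TAC were -4.28 ± 0.57 (SE) for Acta1, 3.38 ± 0.31 for Lcn2, 2.16 ± 0.37 for Gpx3 and 2.34 ± 0.44 for Star, with edgeR Benjamini-Hochberg adjusted p-values of 0.00785, 0.000447, 0.0313 and 0.0397. The immediate early gene Arc (4.04 ± 0.72) and the complement protease gene Masp1 (2.51 ± 0.35) were also higher. Ndufs5 (-5.30 ± 0.42, uncertain as above), Hrasls (-3.58 ± 0.50) and Pnck (-2.39 ± 0.41) were lower. Arc lies on chromosome 15 from 74669083 to 74672570, near Mkl1, and Masp1 (23449417 to 23520815) and Hrasls (29209695 to 29230531) lie on chromosome 16, near Mkl2. All 6 genes higher after sham were also higher after TAC, and Acta1, Mkl1 and Ndufs5 were lower after both. Nppb had 647 CPM in dKO and 688 in control, an estimate of -0.09 (edgeR, Benjamini-Hochberg adjusted p = 0.956). Myh7 had 3921 and 790 CPM, with 1599 in control TAC replicate 3 against 393 and 379 in the others, an estimate of 2.31 ± 0.52 (edgeR, Benjamini-Hochberg adjusted p = 0.091). Srf had 55.4 and 94.7 CPM, an estimate of -0.77 ± 0.18 (edgeR, Benjamini-Hochberg adjusted p = 0.101).

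Of 35 MRTF-SRF targets, Acta1 and Cnn2 fell (1 higher and 10 lower adjusted over the list alone), with a median of -0.44. The camera Benjamini-Hochberg adjusted p was 1.1e-05, and the adjusted p = 0.728 with an estimated correlation. Acta2 (-1.95 ± 0.42), Myl9 (-1.88), Pdlim7 (-1.21) and Actc1 (-1.01) did not pass over all genes. Ankrd1, at 1.01 ± 0.29, had the highest estimate and did not pass either. Acta2, Tagln and Cnn1 are also on the list of pericyte and smooth muscle markers, of which 1 of 14 had a positive estimate, and of 20 endothelial markers 0 had one. When dKO sham replicate 1 and dKO TAC replicate 2 were left out, 11 of the 35 were lower and 1 higher, with a median of -0.68, and the median was -0.67 with only dKO TAC replicate 2 left out.

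**Figure D4:**
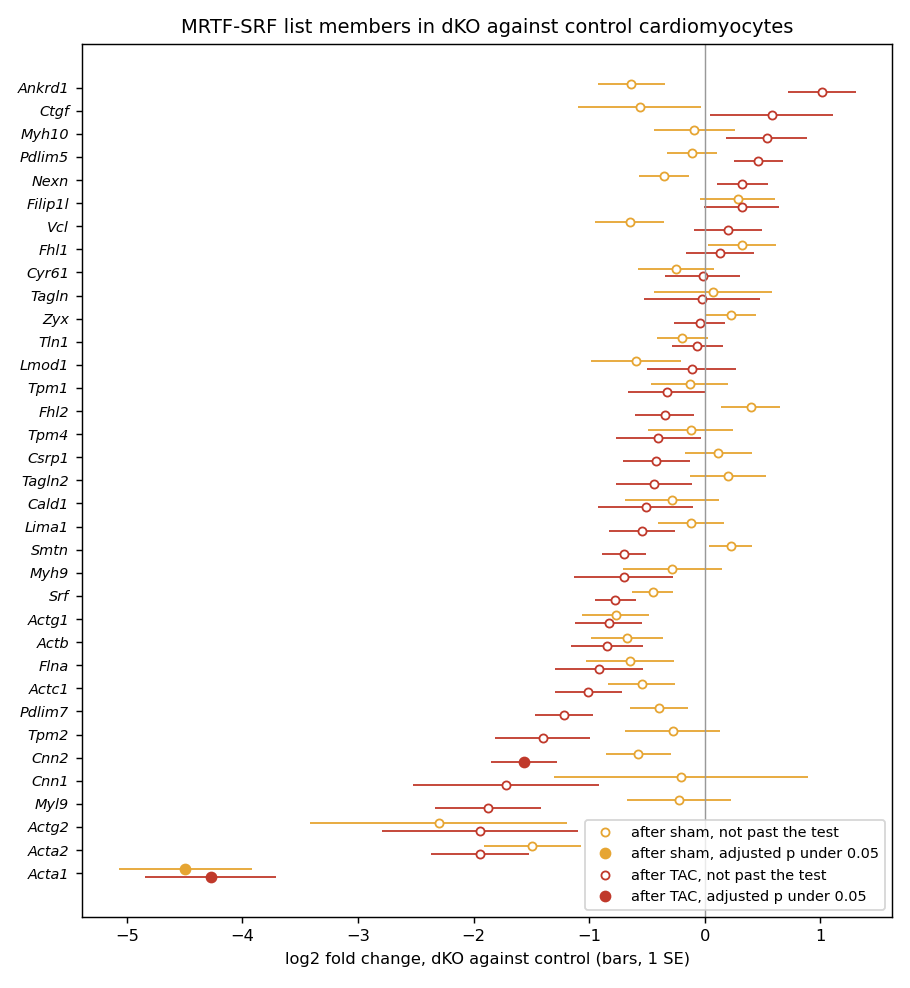
Log2 differences between dKO and control for the 35 MRTF-SRF target genes, after sham and after TAC, with bars of 1 SE. Filled points passed the test over all genes: Acta1 in both, at -4.50 after sham and -4.28 after TAC, and Cnn2 after TAC at -1.56.

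Of 20 intercalated disc genes Cxadr rose (4 higher and 1 lower adjusted over the list alone), with a median of 0.25, and of 18 fetal and hypertrophic genes Acta1 fell (7 higher and 2 lower adjusted over the list alone), with a median of 0.58. Atrophy and autophagy genes had a median of 0.29 (3 of 21 higher adjusted over the list alone). These 3 lists had an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). Fatty acid oxidation genes had a median of -0.32, glycolysis genes 0.25 and interferon response genes -0.31, with 0, 0 and 1 lower adjusted over the list alone, and an adjusted p = 0.866 with an estimated correlation (camera, Benjamini-Hochberg). Each of these calls was lost when single libraries were left out. Fatty acid oxidation stood at -0.04 without control TAC replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.874). Glycolysis stood at 0.115 without control TAC replicate 3 (0.351). Its call was also lost without dKO TAC replicate 3 (0.124) and with the length trend removed (0.106). The interferon response stood at -0.19 without control TAC replicate 3 (0.216). Its call was also lost without control TAC replicate 2 (0.194), dKO TAC replicate 1 (0.155) or dKO TAC replicate 3 (0.0787). Medians that moved and stayed called were -0.51 for fatty acid oxidation without control TAC replicate 3, -0.51 for the interferon response without control TAC replicate 1, 0.16 for glycolysis and 0.47 for the intercalated disc without dKO TAC replicate 2, and 0.32 for the fetal program without control TAC replicate 1. Markers of other cells had lower estimates in dKO TAC. All 20 endothelial markers had negative estimates, with a median of -0.38 and 56 against 70.2 CPM, and the adjusted p = 0.736 with an estimated correlation (camera, Benjamini-Hochberg). Atrial markers had a median of -0.98 (3 of 8 lower adjusted over the list alone), with 4.85 CPM of Myl4, the atrial myosin light chain, against 70.3. Blood markers had a median of -1.46, nerve and epicardial markers -0.996 and mitochondrially encoded genes -0.27, all called by camera and at an adjusted p = 0.728 with an estimated correlation (camera, Benjamini-Hochberg). Pericyte and smooth muscle markers, which share 3 genes with other lists, had a median of -0.34 and an adjusted p = 0.831 with an estimated correlation (camera, Benjamini-Hochberg). The endothelial and pericyte calls were lost without dKO TAC replicate 3 (medians of -0.22 and -0.16, camera Benjamini-Hochberg adjusted p of 0.073 and 0.231), while without dKO sham replicate 1 and dKO TAC replicate 2 their medians were -0.625 and -0.762, both called. The pericyte call was also lost without control TAC replicate 2 (-0.21, 0.124), and those of nerve and epicardial markers and mitochondrially encoded genes without control TAC replicate 1 (-0.78 and -0.13, 0.102 and 0.214). The mitochondrially encoded call was also lost without dKO TAC replicate 2 (-0.235, 0.307). Its median, -0.27 with all libraries, stayed called and lay between -0.62 (without dKO TAC replicate 1) and -0.43 (without dKO sham replicate 3) when any 1 library was left out except control TAC replicate 1, dKO TAC replicate 2 and control sham replicate 2. The atrial median was -0.65 without control TAC replicate 3, still called.

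Genes that rose with TAC in control were compared with genes lower in dKO TAC. Acta1 was the 1 gene in both, against 0.343 for independent lists, and 0 of 51 genes lower with TAC were higher in dKO TAC. Simulations with no effect of TAC or genotype gave 0 in all 20 runs, a value that leaves out the effects both comparisons hold. The comparisons share the control TAC libraries, which are too few to split, so part of any excess may come from them. The overlap was 0 without control sham replicate 1, control sham replicate 3, control TAC replicate 2 or dKO TAC replicate 3, was 2 without control TAC replicate 1 and was 9 without dKO sham replicate 1. Acta1 itself had an edgeR Benjamini-Hochberg adjusted p of 0.0708 in dKO TAC without dKO TAC replicate 3.

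The total of genes called in dKO after TAC, 63 with all libraries, was with 1 library left out 16 for control TAC replicate 1 (13 of them among the 63), 23 for control TAC replicate 2 (21), 28 for control TAC replicate 3 (22), 26 for control sham replicate 1 and 31 for control sham replicate 3. It was 252 for dKO sham replicate 1, 33 for dKO sham replicate 2, 11 for dKO TAC replicate 1 (10 among the 63) and 8 for dKO TAC replicate 3. Without dKO sham replicate 1 and dKO TAC replicate 2, 353 genes were higher and 155 lower, and all 63 were among them.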

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

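The interaction tests of the gene lists were planned, while the tests of transcript length, other cells, near copies, linked variants, MRTF-SRF targets and the matrix genes were chosen only after the result was seen. In 10 lists the response to TAC differed between genotypes by the planned camera test of the interaction, at adjusted p-values (Benjamini-Hochberg) from 9.5e-07 to 0.0426. None of the 10 was called with an estimated correlation (camera, Benjamini-Hochberg adjusted p-values of 0.728 to 0.866) and no single gene passed by edgeR, with 697 at an unadjusted p under 0.05. Each median below is the log2 response in dKO minus that in control.

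The median of intercalated disc genes was 0.507, with 19 of 20 estimates positive. The median of the fetal and hypertrophic program was 0.562, with 13 of 18 positive, and 0.299 with the transcript-length trend removed, still called. YAP-TEAD targets stood at 0.195 with 14 of 20 positive, costamere and focal adhesion genes at 0.228 with 21 of 31 positive, and oxidative phosphorylation genes at -0.681 with 2 of 45 positive. All 3 calls were lost without dKO sham replicate 1, at medians of -0.0532, 0.104 and -0.0195 (camera, Benjamini-Hochberg adjusted p of 0.391, 0.189 and 0.551). Costamere genes also lost their call without control TAC replicate 1 (0.2766, 0.0541) or control TAC replicate 3 (0.1538, 0.141). The same held with the length trend removed (0.1067, 0.257). The YAP-TEAD call was also lost without control TAC replicate 1 (0.0836, 0.066), and its median stayed called at 0.0638 without control sham replicate 2, at 0.12 without control TAC replicate 2, and from 0.303 to 0.348 without any 1 of control sham replicate 1, control TAC replicate 3 and dKO sham replicates 2 and 3. The interferon response stood at -0.476 with 2 of 19 positive, and at -0.2475, not called, without dKO sham replicate 3 (0.185). Its call was also lost without control TAC replicate 2 (-0.4707, 0.0681) or control TAC replicate 3 (-0.4067, 0.0827). The medians without dKO sham replicate 1 and dKO TAC replicate 2 together were -0.825 for the interferon response and -0.189 for oxidative phosphorylation, both called, and 0.035 for YAP-TEAD targets, not called. Among markers of other cells, the medians were -0.479 for endothelium, with 0 of 20 positive, -0.456 for pericytes and smooth muscle, -1.06 for nerve and epicardium, and -1.82 for the atrium. With the same 2 libraries left out the endothelial and pericyte medians were -0.816 and -0.887, both called (camera, Benjamini-Hochberg adjusted p of 1.15e-07 and 0.000442), and the endothelial median was -0.31 without dKO TAC replicate 3, still called. The pericyte median was -0.198 without dKO TAC replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.366), which ended its call. Leaving out control sham replicate 1 or 3, or control TAC replicate 2 or 3, also ended it. So did leaving out dKO sham replicate 2 or 3 or dKO TAC replicate 1 (0.0563 to 0.295 in these fits). The nerve call was lost without control sham replicate 3 (-0.706, 0.191). Without control TAC replicate 1, dKO sham replicate 2 or 3 or dKO TAC replicate 2 it was lost too (0.0574 to 0.149). With the length trend removed both calls were lost (0.0962 and 0.0732). Without control sham replicate 2 the pericyte and nerve medians were -0.713 and -1.96, both called. The atrial list includes Myl7 (-6.34 ± 1.68), Myl4 (-5.69 ± 1.28) and Sln (-6.36 ± 1.94), which are abundant in atrial cells and near absent from ventricular ones. Without the same 2 libraries atrial markers were called higher in dKO already after sham, at a median of 1.51, and lower after TAC, at -1.02 (camera, Benjamini-Hochberg adjusted p of 0.000122 and 0.00219). In that fit the atrial interaction thus held a difference after sham. With the length trend removed the sham median was 1.01, not called (0.586).

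The libraries dKO sham replicate 1 and dKO TAC replicate 2 stood apart from their groups. A larger share of other cells was looked for in the fibroblast, endothelial, macrophage and pericyte medians. The highest of the 4 was -0.133 in dKO sham replicate 1, and in dKO TAC replicate 2 they lay 0.863 ± 0.309 (SE over genes) apart. These medians still hold the length trend. It moved transcripts of at most 1963 nt by 1.11 and 0.473, and those of at least 10502.6 nt by -0.879 and -0.473. Neither library can therefore be judged for a larger share of other cells. A trend with transcript length, as RNA quality or library preparation can give, may account for much of the nuclear part: it took up 0.375 and 0.351 of the variance of their deviations, at most 0.013 in control libraries, and 0.202 to 0.408 in the other dKO libraries, which are measured against the odd ones. For the low mitochondrially encoded counts the trend alone would give a rise. Transcripts of at most 1963 nt rose by 1.11 in dKO sham replicate 1 and 0.473 in dKO TAC replicate 2. In dKO TAC replicate 2 the mitochondrially encoded genes lay at -0.791 ± 0.112 (SE over genes), with 8 of 9 below 0. This argues against a trend with length alone there. In dKO sham replicate 1 they lay at -0.67 ± 0.443, with 6 of 9 below 0. This is within 2 SE of 0, so a fall is not shown there. It also lies more than 2 SE below the 1.11 of short transcripts. For these 9 genes that argues against a rise of that size, though the SE leaves out the spread between libraries. The deviations also rose with the GC content of transcripts, at a Spearman rho across genes of 0.424 in dKO sham replicate 1 and 0.436 in dKO TAC replicate 2. It was -0.19 to 0.129 in control libraries and -0.456 to -0.328 in the other dKO libraries. Length and GC content were not separated. Whether a trend with GC content lowers the mitochondrially encoded genes was not tested, so such a trend stays open. No batch is given in the sources used here, and a difference between these mice was not tested.

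Few genes differed between genotypes after sham or TAC, and a reading of them has to weigh near copies, linked variants and lost MRTF-SRF transcription. An exchange of reads between Ndufs5 and BC002163 would leave their sum in place, yet the sum was higher in dKO by a log2 of 1.46 ± 0.492 (SE) after sham and 0.757 ± 0.203 after TAC. The limit of 1 for excluding an exchange was set after the values were seen and was passed by less than 2 SE (132 against 42.9 CPM as means, with 227 in dKO sham replicate 1), and reads matching both genes may have been lost in one genotype, so it cannot be told apart. Sums of the other pairs were not tested. Eif3j2 with Eif3j1 had 26.5 CPM in control and 20.1 in dKO after sham, and 23.2 and 22.8 after TAC. In the same order Gm20305 with Polr2k had 5.62 and 7.11, and 4.55 and 5.24. Gm14085 with Slc28a2 had 45.1 and 35.2, and 36.7 and 24.5. Rpl3-ps1 with Rpl3 had 95.4 and 140, and 162 and 238. Gm16399 with Cox6c had 545 and 785, and 418 and 410. Variants of another strain linked to the targeted genes are a candidate explanation: 7 of 62 called genes with a position lay within 20 Mb of Mkl1 or Mkl2 (11.3% against 4.03% of tested genes, two-sided Fisher's exact test, p = 0.012). The excess lay mostly near Mkl2, with 5 of 62 (8.06% against 1.58%), and near Mkl1 there were 2 of 62 (3.23% against 2.45%). These genes include Arc, Psca, Etv5, Hrasls, Masp1 and Rtn4r. Loss of MRTF-SRF transcription is also open: 2 of 18 genes lower in dKO TAC, Acta1 and Cnn2, were on the list of 35 targets among 14712 genes (two-sided Fisher's exact test, p = 0.000821). Both had been seen lower before this test was chosen, so it adds little to them, and Acta1 lost its call without dKO TAC replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.0708). Pericyte and smooth muscle markers (median -0.344, 1 of 14 positive) and endothelial markers (-0.38, 0 of 20 positive) also had lower estimates in dKO TAC, and a lower share of these cells was not tested as a source of the low smooth muscle genes.

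Of 34 matrix genes 23 rose after TAC in each genotype, in cells enriched for cardiomyocytes, and the list was not called with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.728 in both). The genes of these lists argue against more fibroblasts alone. The matrix median exceeded the fibroblast marker median by a log2 of 1.76 ± 0.465 (SE over genes) in control and 2.31 ± 0.491 in dKO. A smaller share of cardiomyocytes alone is argued against too, since the highest and lowest of the fibroblast, endothelial, macrophage and pericyte medians lay 1.24 ± 0.107 apart in control and 1.26 ± 0.199 in dKO. All these SEs treat genes as replicates, so both arguments leave out the spread between libraries. What stays open is matrix transcription that rose within the fibroblasts or other cells present, within cardiomyocytes, or both, which these libraries may not separate.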

How the results depend on the processing

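The runs without dKO sham replicate 1 and dKO TAC replicate 2 together, and with the transcript-length trend removed, were chosen only after seeing the data, and all others were planned. No named gene past its threshold, in the fit of all libraries or in an alternative, changed direction. Medians of 4 called lists changed sign as their calls were lost. The YAP-TEAD interaction went to -0.0486 with quality weights and -0.0532 without dKO sham replicate 1. Cytokine genes for TAC in dKO went to -0.0134 with quality weights and -0.128 without the 2 libraries. Mitochondrially encoded genes in dKO after TAC went to 0.0551 with quality weights. Oxidative phosphorylation genes in dKO sham went to -0.0809 with quality weights, -0.0387 without dKO sham replicate 1 and -0.039 without the 2 libraries. Counts are given as higher and lower in the order TAC in control, TAC in dKO, dKO after sham, dKO after TAC and interaction. DESeq2 called 699 and 239, 1109 and 1164, 26 and 28, 186 and 100, and 8 and 3, with an overlap of 15 between genes higher with TAC in control and lower in dKO TAC. With no expression filter they were 652 and 284, 705 lower in TAC in dKO, 22 and 31, 78 and 51, and 1 and 4, with an overlap of 10. Limma-voom called 141 higher with TAC in control. With sample quality weights it called 3322 and 2965, 3024 and 2945, 214 and 294, 1522 and 1626, and 1157 and 1342, with a correlation of the responses of 0.615 and an overlap of 1250, at weights from 0.082 for dKO sham replicate 1 to 3.17 for control TAC replicate 2. A fit of only the groups compared, on fewer samples, called 2 and 0 for TAC in control, 164 lower for TAC in dKO and 1 lower after sham, with an overlap of 0. The stricter filter, which tests fewer genes, left 33 lower with TAC in control and a correlation of 0.733. Without dKO sham replicate 1 and dKO TAC replicate 2 the counts were 501 and 270 for TAC in control, 353 and 155 for dKO after TAC, and 2 higher for the interaction, with a correlation of 0.626 and an overlap of 18. With the length trend removed 102 were lower with TAC in control, 7 lower after sham, 91 and 41 differed after TAC, and 1 was lower in the interaction, with an overlap of 2. An estimated correlation left 2 of 68 list calls, and fry 2. Where the construction does not show it, the cause was not tested. DESeq2 size factors, upper quartile normalization and leaving out mitochondrially encoded genes kept every count within 1.5 times.

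Leaving out each library in turn gave 2 to 875 higher and 0 to 255 lower for TAC in control, 161 to 810 and 49 to 732 for TAC in dKO, 4 to 10 and 1 to 3 for dKO after sham, 6 to 164 and 2 to 88 for dKO after TAC, and 0 to 1 and 0 for the interaction, with a correlation of 0.64 to 0.732 and an overlap of 0 to 9. The group left with 2 libraries shared the spread pooled over all groups. Of 108 values for named genes, 34 lost their call without control sham replicate 1, 32 without control sham replicate 3 and 30 without control TAC replicate 2. The 108 include values not called with all libraries, which could not lose a call, so the share lost among called values was larger. Over all alternatives, named genes, the uncalled ones included, kept their side of the threshold 2270 times, lost a call 276 times and gained one 28 times. Called lists kept their call 1438 times and lost it 248 times.

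The replicate numbers do not pair the samples by the labels. Of 18 same-numbered pairs 9 had correlated deviations over 0.1, from -0.474 to 0.35, and 3 of 12 libraries correlated best with their own number. With the number as a replicate block, 252, 937, 10, 41 and 0 genes were called, with 26 higher in dKO after TAC. Depth limits little in abundant genes, since 3 counts correspond to at most 0.184 CPM, while some genes near that level in a group, such as Sprr1a in control sham, are given as levels without a fold. The folds given for Sprr1a in dKO and Cxcl10 in control also start from low levels after sham. These were 0.18 to 0.828 CPM and 0.183 to 0.372 CPM, so their size is uncertain.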

Other observations

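The list tests of this part were planned, while the counts over other splits of the samples were chosen only after the result was seen. Several stress programs of the heart were not called by camera in any comparison with all libraries, and the medians after TAC in control and in dKO are given with the genes called by edgeR. Heat shock and small chaperone genes stood at 0.13 and -0.09, with 0 and 1 of 17 called, the gene being Hsp90aa1 (1.09 ± 0.24 in dKO, 1 adjusted over the list alone). Endoplasmic reticulum stress genes stood at 0.19 and -0.03, with Ddit3 lower in dKO (-1.71 ± 0.44, 1 adjusted over the list alone). Without dKO sham replicate 1 and dKO TAC replicate 2 this list was called lower in dKO than control after TAC. Its median was then -0.346 (camera, Benjamini-Hochberg adjusted p = 0.00978). The p53 list stood at 0.33 and 0.15, with Gdf15 (2.74) and Zmat3 (0.86) higher and Gadd45a (-1.75) lower in dKO, and 4 higher and 1 lower in control adjusted over the list alone. The oxidative stress list stood at 0.13 and 0.15, and in dKO Gpx3 (2.45 ± 0.38) and the oxidase gene Nox4 (3.83 ± 1.06) rose while Osgin1 (-1.45) fell. In dKO the adrenergic receptor kinase gene Grk5 rose (1.18 ± 0.23) in a list of adrenergic and natriuretic genes at -0.11 and -0.06.

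Genes of the adult sarcomere stood at -0.06 after TAC in control and -0.03 in dKO, with 0 of 26 called in control and 1 higher and 2 lower in dKO. Calcium handling genes stood at -0.10 and 0.08, with Hrc, a calcium-binding protein of the sarcoplasmic reticulum, lower in dKO (-1.53 ± 0.34). The mean of that list in dKO was -0.27, opposite in sign to its median. Immediate early genes, which cell isolation also induces, stood at -0.23 and -0.60 with 0 of 22 called by edgeR, 0 when adjusted over the list alone as well. With dKO sham replicate 1 and dKO TAC replicate 2 left out, the list was called lower after TAC in dKO. Its median was then -0.929 (camera, Benjamini-Hochberg adjusted p = 0.0381). Cardiac transcription factors stood at -0.20 and -0.00421, with 0 of 20 called. For the matrix list the camera direction was higher while the medians were -0.04 in dKO after sham, -0.28 in dKO after TAC and -0.14 for the interaction, none of them called. The median and the camera direction also differed in sign for YAP-TEAD targets in dKO after TAC, at -0.19 with a mean of 0.09, likewise uncalled. Among genes that rose with TAC in control and were higher still in dKO TAC were Fstl3, Lcn2, Serpinb1c and Star, against 0.856 for independent lists of calls that share the control TAC libraries.

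Other splits of the same 6 libraries were fitted as a check of each comparison of 2 groups. There are 10 such splits, too few for a share under 0.05, and the real one was the 1 split of 10 with as many genes as the real value in each case. The other splits mix the real groups, so any real difference widens their spread and lowers their counts. They do not show how many genes unchanged groups would give. The real value and the highest of the other splits were 331 and 0 for TAC in control, 1087 and 0 for TAC in dKO, 10 and 0 for dKO after sham, and 63 and 1 for dKO after TAC. For the interaction the real value was 0, which all 100 splits drawn reach by definition, so their count says nothing about chance, and the highest of the others was 2.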
